A study of Mus musculus with 12 samples.

How the data were processed

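The series holds 12 RNA sequencing libraries from C57BL/6 mouse bone marrow, 2 per group in 6 groups. Per the labels' protocols, marrow was harvested from individual mice, HSPC were purified with a CD117 positive selection kit, the mutant clone was sorted by FACS, Ly6G+ myeloid cells were sorted by FACS, and total RNA was extracted with RNeasy kits before standard Illumina library preparation. Per the submitters' processing notes, bcl2fastq, CASAVA 1.8 and kallisto were used with the genome build mm10. The kallisto version, the annotation release and the way transcripts were joined to genes are not stated.

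The deposited table gives TPM, the share of each gene in a library's transcripts corrected for length, for 28987 Ensembl genes and 12 libraries, although it is named a table of counts. The values are not whole numbers, and every library sums to between 933370 and 981994. The deposited TPM carry no scaling between libraries and no read numbers, so no depth, counting interval or floor can be given for any value. A gene symbol was found for 27458 of the identifiers (94.7%). Coordinates are those of the GRCm38 annotation. All 12 columns were used.

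The groups and comparisons, the gene lists and the tests were set before the data were examined. The planned count model needs read counts and was replaced by the planned fallback for normalized values, limma 3.58.1 in R 4.3.3 on log2(TPM + 1). The added 1, the pseudocount, compresses the fold change of a gene that lies near or below 1 TPM in a group. TPM were first scaled between libraries with trimmed mean factors (TMM, unweighted, trimming 0.3 of the log ratios and 0.05 of the levels on each side). Genes were kept when at least 2 libraries of the fit had 1 TPM or more. Each fit had group means only, and moderated the variance with a trend on the mean level and robustly. The SE and p-values of a comparison thus rest on a spread pooled over all groups of its fit, not on that of the compared groups. The 4 HSPC groups shared 1 fit of 8 libraries (4 residual degrees of freedom), the Ly6G+ groups had a fit of 4 libraries (2 residual degrees of freedom), and the genotype by cell type term and the comparison of wild type populations used all 12 (6 residual degrees of freedom). The scaling and the moderation of the variance were chosen before any number of passing genes was seen. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and genes with an adjusted p under 0.05 are called.

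Of 30 gene lists written before the data were examined, 29 were tested and the list of sex-linked genes was set aside. Each was tested against all other genes with camera at the preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated from the residuals and fry, which does not compare a list with other genes, were alternatives. None of the 86 calls in 261 tests held with an estimated correlation. These correlations rest on 2 to 6 residual degrees of freedom and reach 0.984 for neutrophil maturation genes in the Ly6G+ fit. Between the wild type populations, 64 of 72 ribosomal protein genes were called lower, yet camera with an estimated correlation gave adjusted p = 0.621. A call lost under this alternative therefore does not show that a list is unchanged. Members were also counted with p-values adjusted over the list alone. The lists are general ones for blood cells and were not chosen on these samples.

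The genes named in the text follow a rule set before the data were examined. Cbl and Runx1 are always given against wild type. Among called genes with a mean log2 level of at least 2 in the fit and no overlap between the libraries of both groups, the 6 largest changes in each direction are named against wild type and the 4 largest for the other terms, leaving out predicted genes. From each list in the text up to 4 members are named, those with the smallest p among called genes in each direction, or the 2 with the smallest p where none is called. For the wild type populations 10 marker genes were fixed. Further members of a list named in a sentence on that list were added for description after their values were seen, namely Ly6g, Ngp, Ltf, S100a8, S100a9, Stfa2l1, Etv5, Egr1, Jun, Dusp1 and Zfp36 in double mutant HSPC, Lck and Gzma against CBL mutant HSPC, and Retnlg, Cxcr2, Mmp8, Il1b, Cxcl2, Dusp1 and Fos in wild type Ly6G+ cells.

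The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter, a replicate block, fits of the libraries of the compared groups alone or of all 12 together, a change of at least a log2 of 1, tests without mitochondrial and haemoglobin genes, and leaving out each library in turn. In a group left with 1 library, that library is assumed to vary like those of the other groups. After the data were seen, unscaled TPM, pseudocounts of 0.1 and 5, no trend and no robust moderation, array weights, and a fit without the 2 libraries that stood apart were added. The method was tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. Each gene had 1 spread, pooled over the libraries of the fit, so a group with a wider spread than the others was not simulated.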

Results

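Messenger RNA was measured by RNA sequencing in 12 mouse bone marrow libraries that form 6 groups of 2. Haematopoietic stem and progenitor cells (HSPC), enriched through the surface receptor CD117, came from wild type, CBL mutant, RUNX1 mutant and CBL/RUNX1 double mutant marrow. Ly6G+ cells, a sorted mature myeloid population, came from wild type and double mutant marrow. CBL is a ubiquitin ligase that ends signalling by growth factor and cytokine receptors, and RUNX1 is a transcription factor of blood cell formation. The series describes the mutant cells as a clone of myelodysplastic syndrome. Per the labels' protocols the mutant clone was sorted by FACS. Any difference in preparation between mutant and wild type cells could not be told apart from an effect of the mutations. Every group mean below rests on 2 libraries, and the values per library are TPM, the length-corrected share of each gene in a library's transcripts, which summed to between 933370 and 981994 over the deposited genes. TPM carry no read numbers, so the depth behind each value is unknown.

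The mRNA of the calprotectin genes S100a8 and S100a9, which neutrophils and their precursors express in large amounts, made up much of nearly every library, HSPC included. They took 28.9% and 31.4% of the TPM in the wild type HSPC libraries, 26.9% and 21.5% in CBL mutant ones, 13.3% and 27.0% in RUNX1 mutant ones and 8.11% and 9.54% in double mutant ones. In Ly6G+ cells they took 34.5% and 33.5% in wild type, and 7.23% and 24.8% in double mutant libraries. Immunoglobulin genes took 6.54% and 6.75% of the wild type HSPC libraries, 0.0756% and 0.103% of the CBL mutant ones, 0.418% and 2.19% of the RUNX1 mutant ones and 0.0084% and 0.00566% of the double mutant ones. In Ly6G+ libraries the immunoglobulin share was 1.66% and 1.58% in wild type and 0.0806% and 0.127% in the double mutant. Ribosomal protein genes took 8.73% and 8.92% of the wild type and 19.2% and 18.5% of the double mutant HSPC libraries.

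The replicates of 2 groups stood far apart. The log2 difference between replicates had an SD of 0.714 across genes in RUNX1 mutant HSPC and of 1.002 in double mutant Ly6G+ cells, against 0.304 to 0.379 in the other 4 groups. The first RUNX1 mutant library correlated most with a double mutant HSPC library, and the first double mutant Ly6G+ library with a CBL mutant HSPC library. In the RUNX1 mutant pair, the first library exceeded the second by a median log2 difference of 1.77 over the stem and progenitor list and differed by -1.75 over the neutrophil list. In the double mutant Ly6G+ pair, the neutrophil list differed by -2.53 and the ribosomal protein list by 0.97.

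**Figure D1:**
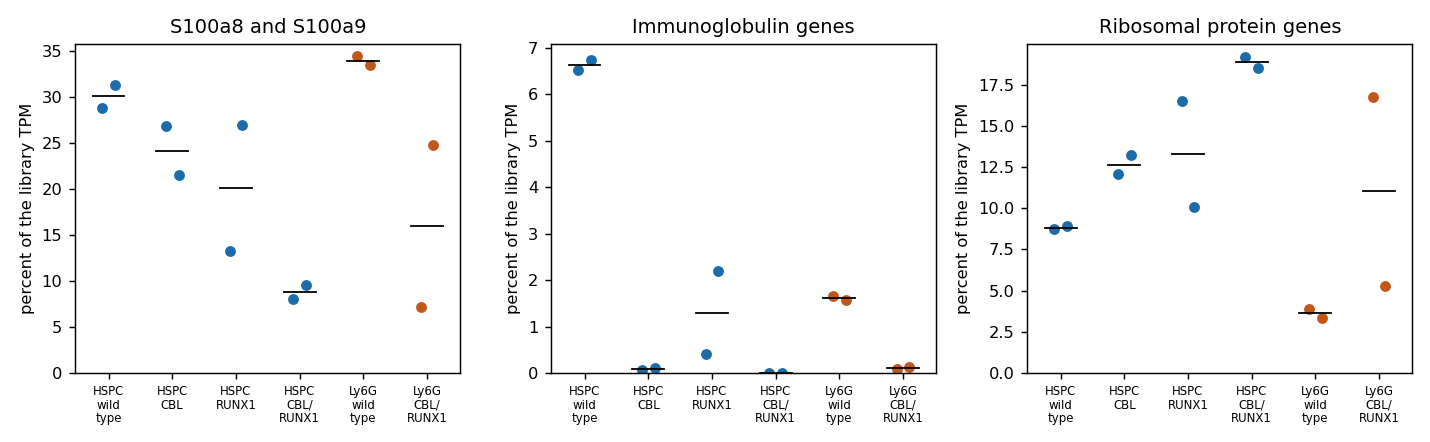
Share of each library's TPM, in percent, that came from S100a8 and S100a9 (left), immunoglobulin genes (middle) and ribosomal protein genes (right). Points are single libraries, 2 per group, with HSPC in blue and Ly6G+ cells in orange, and bars are group means. The immunoglobulin share is 6.54% and 6.75% in wild type HSPC and below 0.01% in double mutant HSPC.

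Mean Cbl and Runx1 mRNA levels were highest in the double mutant within each cell type. Cbl (ENSMUSG00000034342, chromosome 9, 44142976 to 44234049) had a mean of 24.5 TPM ± 9.28 (SD) in wild type HSPC, 77.5 ± 5.41 in CBL mutant, 28.5 ± 5.12 in RUNX1 mutant and 109 ± 8.56 in double mutant HSPC. Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149) had 11.997 TPM ± 1.01 in wild type, 14.3 ± 2.95 in CBL mutant, 108 ± 88.3 in RUNX1 mutant and 252 ± 6.44 in double mutant HSPC. The RUNX1 mutant libraries differed widely, at 170.2 and 45.3 TPM. In Ly6G+ cells, Cbl was 43.8 TPM ± 1.68 in wild type and 134 ± 14.1 in the double mutant, and Runx1 was 9.95 ± 1.68 and 134 ± 11.2. The deposited values do not separate the endogenous genes from any introduced sequence.

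**Figure D2:**
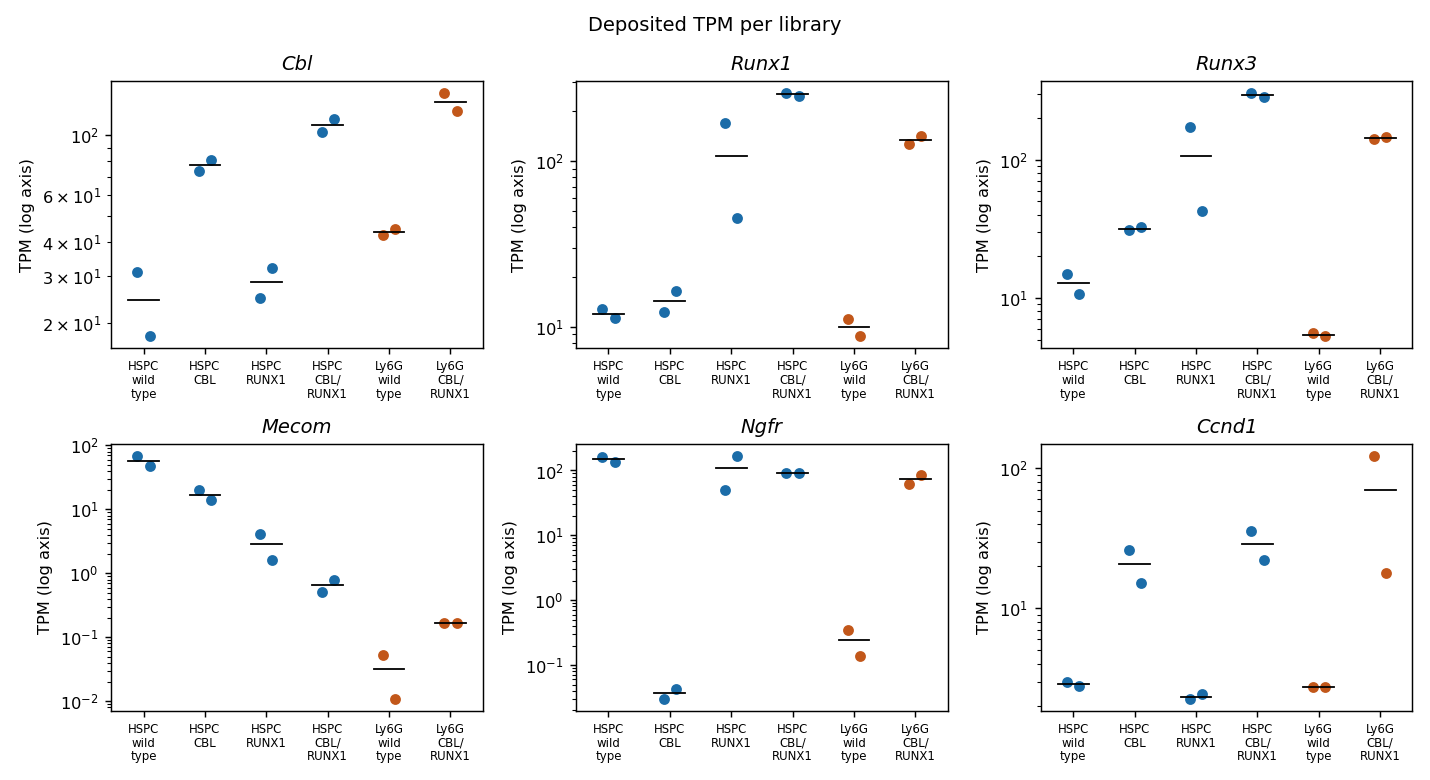
Deposited TPM per library, on log axes, for Cbl, Runx1, Runx3, Mecom, Ngfr and Ccnd1. Points are single libraries, 2 per group, with HSPC in blue and Ly6G+ cells in orange, and bars are group means. Runx1 spans 45.3 to 257 TPM over the 6 libraries with a RUNX1 mutant and 8.77 to 16.4 TPM over the other 6.

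The comparison of CBL mutant with wild type HSPC asked what the CBL mutation does alone. T cell and natural killer cell genes rose: Tcf7, a T lineage transcription factor, by a log2 fold change of 4.42 ± 0.25 (SE, adjusted p = 0.0013), the T cell receptor gene Trbc1 by 4.14, Tcrg-C1 by 3.18, the kinase gene Lck by 3.24 and the granzyme gene Gzma by 3.22. The values do not separate a change within the progenitors from a higher share of T and natural killer cells, which was not tested. Ccnd1, which encodes cyclin D1, rose by 2.13 ± 0.30 (SE, adjusted p = 0.0408), and BC100530 of the stefin family by 3.56 and Mc5r by 2.47. Immunoglobulin segments fell, among them Igkv11-106 with -9.43, Igkj1 with -7.88, Ighg2c with -7.63, Ighg2b with -7.36 and Igkj2 with -7.31. Reads of such near-identical segments, and of the stefin genes, can be shared among family members. Ngfr, whose deposited values do not separate the mouse gene from any introduced sequence, fell by 7.60 ± 0.61 (SE), Pf4, a platelet chemokine gene, by 3.42 and Mecom, a stem cell transcription factor gene, by 2.12. Ngfr lay far below the pseudocount of 1 in the CBL mutant libraries, so the size of its fall is a lower bound. Cbl itself had a log2 fold change of 1.28 ± 0.30 (SE, adjusted p = 0.185) and Runx1 one of -0.16 (adjusted p = 0.88).

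Of the 29 gene lists, 9 passed the list test in this comparison. Of 11 T and natural killer cell genes, 4 rose (7 when adjusted over the list alone), with a median log2 fold change of 1.13 (camera, adjusted p = 8.89e-08, and adjusted p = 0.513 with an estimated correlation). Of 15 RAS-MAPK output genes, 1 rose, Ccnd1 (1 when adjusted over the list alone), with a median of 0.25. The median was 0.66 over MHC class II and dendritic genes and 0.12 over ribosomal protein genes. It was -1.32 over erythroid genes, -0.35 over cell cycle genes, -0.31 over antioxidant genes, -0.21 over nuclear respiratory chain genes and -0.23 over mitochondrially encoded ones. No member of these 7 lists passed, over all genes or when adjusted over the list alone. The calls of these 7 lists and of the RAS-MAPK list were lost, at adjusted p = 0.772 with an estimated correlation. With TPM left unscaled between libraries, which moved the median of all genes to 0.33, the medians of the cell cycle, antioxidant, respiratory chain and mitochondrially encoded lists became 0.04, 0.10, 0.20 and 0.18. The first wild type library differed from the second by a median of -0.23 over both respiratory chain and ribosomal protein genes. Mean log2 levels over these lists were 7.34 and 7.47 against 7.48 and 7.71 in wild type, and 10.01 and 10.10 against 9.83 and 10.05. Among the lists that did not pass were medians of 0.30 for stem and progenitor identity (1 gene lower, Mecom, and 3 higher and 3 lower when adjusted over the list alone), -0.43 for neutrophil maturation, -0.58 for primary granules, -0.11 for interferon response, -0.06 for NF-kB and inflammation, -0.14 for mitochondrial dynamics and -0.26 for RUNX1-related genes. The interferon, NF-kB, mitochondrial dynamics and RUNX1-related medians were 0.22, 0.24, 0.25 and 0.15 with unscaled TPM, and the neutrophil maturation and primary granule ones -0.02 and -0.17.

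In total 69 of 12421 genes passed (limma, adjusted p under 0.05), 39 higher and 30 lower in CBL mutant HSPC. The count was 4 without either wild type library, 11 and 7 without CBL mutant library 1 and 2, 701 and 725 without RUNX1 mutant library 1 and 2, and 24 without either double mutant library. A fit of the 4 libraries of these groups alone gave 852, and array weights gave 548.

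The comparison of RUNX1 mutant with wild type HSPC asked what the RUNX1 mutation does alone. Mecom fell by 4.51 ± 0.27 (SE, adjusted p = 0.00298), from 57.9 TPM ± 14.97 (SD) to 2.89 ± 1.79. Cldn1, a tight junction gene, fell by 3.70 ± 0.22 (SE, adjusted p = 0.00298). Outside the rule for named genes, and so chosen after their values were seen, the other called genes were Psma8, a proteasome subunit gene with a log2 fold change of 2.92, Gm1673 with -3.21, Gm16569 with -3.95 and an unnamed gene, ENSMUSG00000076660, with -5.47. Runx1 had a log2 fold change of 2.26 ± 0.40 (SE, adjusted p = 0.142) and Cbl one of -0.28 ± 0.30 (SE, adjusted p = 0.621). These SE pool the spread of the 4 HSPC groups and can understate that of the RUNX1 mutant pair, which had 170.2 and 45.3 TPM of Runx1.

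The list test passed 11 lists. Stem and progenitor genes had a median log2 fold change of 1.51, with 0 of 22 called higher and 1 lower (12 higher and 2 lower when adjusted over the list alone), and adjusted p = 2.13e-06 with the preset against adjusted p = 0.739 with an estimated correlation. Megakaryocyte and platelet genes had a median of 1.16, with no call over all genes and 7 higher when adjusted over the list alone (adjusted p = 0.721 with an estimated correlation). Among them Treml1 had 3.43 (adjusted p = 0.16) and Clec1b 1.22 (adjusted p = 0.148). Mean log2 levels in the first and second RUNX1 mutant library were 4.96 and 3.38, against 2.97 and 3.05 in wild type, over stem and progenitor genes and 3.64 and 2.51, against 1.81 and 1.87, over megakaryocyte and platelet genes. RUNX1-related genes had a median of 0.17, with 6 higher when adjusted over the list alone (adjusted p = 0.721 with an estimated correlation for the list). The other 8 passed lists had negative medians: neutrophil maturation -0.95, erythroid -1.03, B-lineage -0.92, T and natural killer -0.40, NADPH oxidase -0.67, cell cycle -0.51, respiratory chain -0.36 and antioxidant -0.28. Their values were adjusted p = 0.842 with an estimated correlation for neutrophil maturation, and adjusted p = 0.739 or adjusted p = 0.721 with an estimated correlation for the others. The first RUNX1 mutant library stood below the second in all 8 of these lists, and the second was close to wild type over neutrophil maturation, erythroid, NADPH oxidase and cell cycle genes. Over neutrophil maturation genes the mean log2 levels were 7.74 and 9.45, against 9.26 and 9.42 in wild type. They were 2.88 and 4.75 against 4.78 and 4.92 over erythroid genes, 7.48 and 8.79 against 8.82 and 8.89 over NADPH oxidase genes, and 5.41 and 6.28 against 6.33 and 6.38 over cell cycle genes. Both libraries were below wild type over B-lineage genes, with 1.59 and 1.76 against 2.508 and 2.51, and over T and natural killer genes, with 0.960 and 1.03 against 1.35 and 1.51. With unscaled TPM, which moved the median of all genes to 0.45, the cell cycle, respiratory chain and antioxidant medians became 0.03, 0.19 and 0.27. Primary granule, interferon, NF-kB, mitochondrial dynamics and RAS-MAPK genes did not pass, with medians of -0.35, -0.18, 0.03, -0.10 and 0.11. The primary granule, interferon and mitochondrial dynamics medians were 0.20, 0.33 and 0.41 with unscaled TPM.

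In total 6 genes passed, 1 higher and 5 lower, of 2055 at an unadjusted p under 0.05. The count was 60 without RUNX1 mutant library 1, which stood above library 2 by a median of 1.77 over the stem and progenitor list, 3621 without RUNX1 mutant library 2 and 1 without either wild type library. Unscaled TPM gave 14 genes, 4 higher and 10 lower, and the 4 libraries of these groups alone gave 1.

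The comparison of double mutant with wild type HSPC asked what both mutations do together. Genes of mature neutrophils fell: Ly6g with a log2 fold change of -5.25, Ngp with -3.53, Ltf, the lactoferrin gene of secondary granules, with -3.39, Padi4 with -2.98 ± 0.48 (SE, adjusted p = 0.0225), Mxd1 with -2.40, S100a9 with -2.54 and S100a8 with -2.37. S100a8 and S100a9 together took 8.11% and 9.54% of the double mutant libraries against 28.9% and 31.4% of the wild type ones. The wild type HSPC shares were near those of wild type Ly6G+ cells, 34.5% and 33.5%. The values do not separate a change within the progenitors from a lower share of neutrophils, which was not tested. This limit also holds for the NADPH oxidase genes below. Primary granule genes went both ways, with Cst7 up by 2.43 and Serpinb1a and Prss57 at -1.45 and -2.03. The progenitor gene Cd34 rose by 2.15 ± 0.52 (SE, adjusted p = 0.0459), from 23.0 to 166 TPM, while Mecom fell by 5.65 ± 0.27 (SE, adjusted p = 0.000326) and Ly6a by 1.996. Runx1 rose by 3.68 ± 0.40 (SE, adjusted p = 0.00901), Runx3 by 3.83 ± 0.42 (SE, adjusted p = 0.00902) and Cbl by 1.54 ± 0.30 (SE, adjusted p = 0.0304).

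Among RAS-MAPK output genes, Ccnd1 rose by 2.38 ± 0.30 (SE), Spry2, a feedback inhibitor gene, by 1.33, Etv5 by 1.53 and Egr1 by 1.42, while Phlda1 fell by 1.28. The largest falls were in immunoglobulin segments, such as Igkj4 with -11.70 ± 0.50 (SE), Igkj2 with -11.61, Igkj5 with -11.50, Igkc with -11.36, Igkv11-106 with -11.26 and Ighg2b with -11.12, and the immunoglobulin share of these libraries was below 0.01%. Where a segment lay near 0 TPM in the double mutant, the pseudocount of 1 limits the size and rank of its fall. Stefin family genes rose, BC100530 by 4.17, Stfa2 by 3.76 and Stfa1 by 2.82, as did Otos by 2.94 and the adaptor gene Grap by 2.88. Among smaller changes, Ddx58 fell by 0.97 and Relb by 1.33. The prohibitin genes Phb and Phb2 rose by 0.70 and 0.65, and the respiratory chain genes Ndufa10 and Sdha by 0.62 and 0.61.

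The list test passed 8 lists, all lost at adjusted p = 0.883 with an estimated correlation. Of 29 neutrophil maturation genes, 18 fell and 4 rose, namely Clec4d (1.89), Stfa1, Stfa2 and Stfa2l1 (22 lower and 4 higher when adjusted over the list alone), with a median of -2.40 (camera, adjusted p = 2.97e-06, and adjusted p = 0.883 with an estimated correlation). Of 7 NADPH oxidase genes, which serve the oxidative burst of phagocytes, 1 fell, Cybb with -2.76 (6 when adjusted over the list alone), with a median of -1.36 (adjusted p = 0.883 with an estimated correlation). Of 71 ribosomal protein genes, 8 rose, Rpl10a by 0.95 and Rpl14 by 0.70 among them (29 when adjusted over the list alone), with a median of 0.46 (adjusted p = 0.883 with an estimated correlation). Of 15 RAS-MAPK output genes, 4 rose and 1 fell (5 and 1 when adjusted over the list alone), with a median of 0.68 (adjusted p = 0.883 with an estimated correlation). Lower medians were found over erythroid genes (-1.33, with Gata1 and Nfe2 called at -1.45 and -1.08), B-lineage genes (-1.13, with Cd79a and Bank1 called at -3.78 and -1.09) and T and natural killer genes (-0.90, with Nkg7 and Ccl5 called at -4.75 and -1.67), and a higher one over 74 respiratory chain genes (0.19, with 2 called). For these 4 lists too the value was adjusted p = 0.883 with an estimated correlation, and the counts when adjusted over the list alone were 2, 4 and 5 lower and 0. Over respiratory chain genes the mean log2 levels overlapped, with 7.64 and 7.86 in double mutant against 7.48 and 7.71 in wild type libraries. The first wild type library differed from the second by a median of -0.23 over this list.

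Of the 21 lists that did not pass here, 6 had medians of 0.65 for stem and progenitor identity (1 gene higher and 2 lower, as when adjusted over the list alone), 0.29 for primary granules (1 higher and 2 lower, as when adjusted over the list alone), 0.51 for RUNX1-related genes (3 higher and 1 lower, and 5 and 2 when adjusted over the list alone), 0.17 for mitochondrial dynamics (2 higher, and 3 when adjusted over the list alone), -0.35 for interferon response (2 lower, and 1 when adjusted over the list alone) and -0.12 for NF-kB and inflammation (1 lower, as when adjusted over the list alone). Others among the 21 had medians of -0.53 for the cell cycle (0 called), -0.12 for p53 and apoptosis (1 higher and 4 lower), 0.02 for endoplasmic reticulum stress (2 higher and 4 lower), 0.18 for Toll-like receptors and alarmins (3 higher and 3 lower) and -0.13 for antioxidant genes (2 higher and 3 lower). When adjusted over the list alone, these 5 had 0 called, 3 higher and 6 lower, 2 and 5, 4 and 4, and 4 and 4. The interferon and NF-kB medians became 0.10 and 0.36 with unscaled TPM, which moved the median of all genes to 0.56, and the cell cycle, p53 and antioxidant ones became 0.09, 0.40 and 0.49. The 3 RUNX1-related genes called higher include Runx1 and Runx3, whose deposited values could hold reads of an introduced RUNX1 sequence.

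In total 1380 of 12421 genes passed, 566 higher and 814 lower in the double mutant, and 770 of them changed by a log2 of at least 1. The count was 28 and 23 without wild type library 1 and 2, 225 and 208 without CBL mutant library 1 and 2, 4381 and 4359 without RUNX1 mutant library 1 and 2, and 56 and 43 without double mutant library 1 and 2. Unscaled TPM gave 3965 genes higher and 417 lower, so the balance of directions depends on scaling, and the 4 libraries of these groups alone gave 4632 genes.

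**Figure D3:**
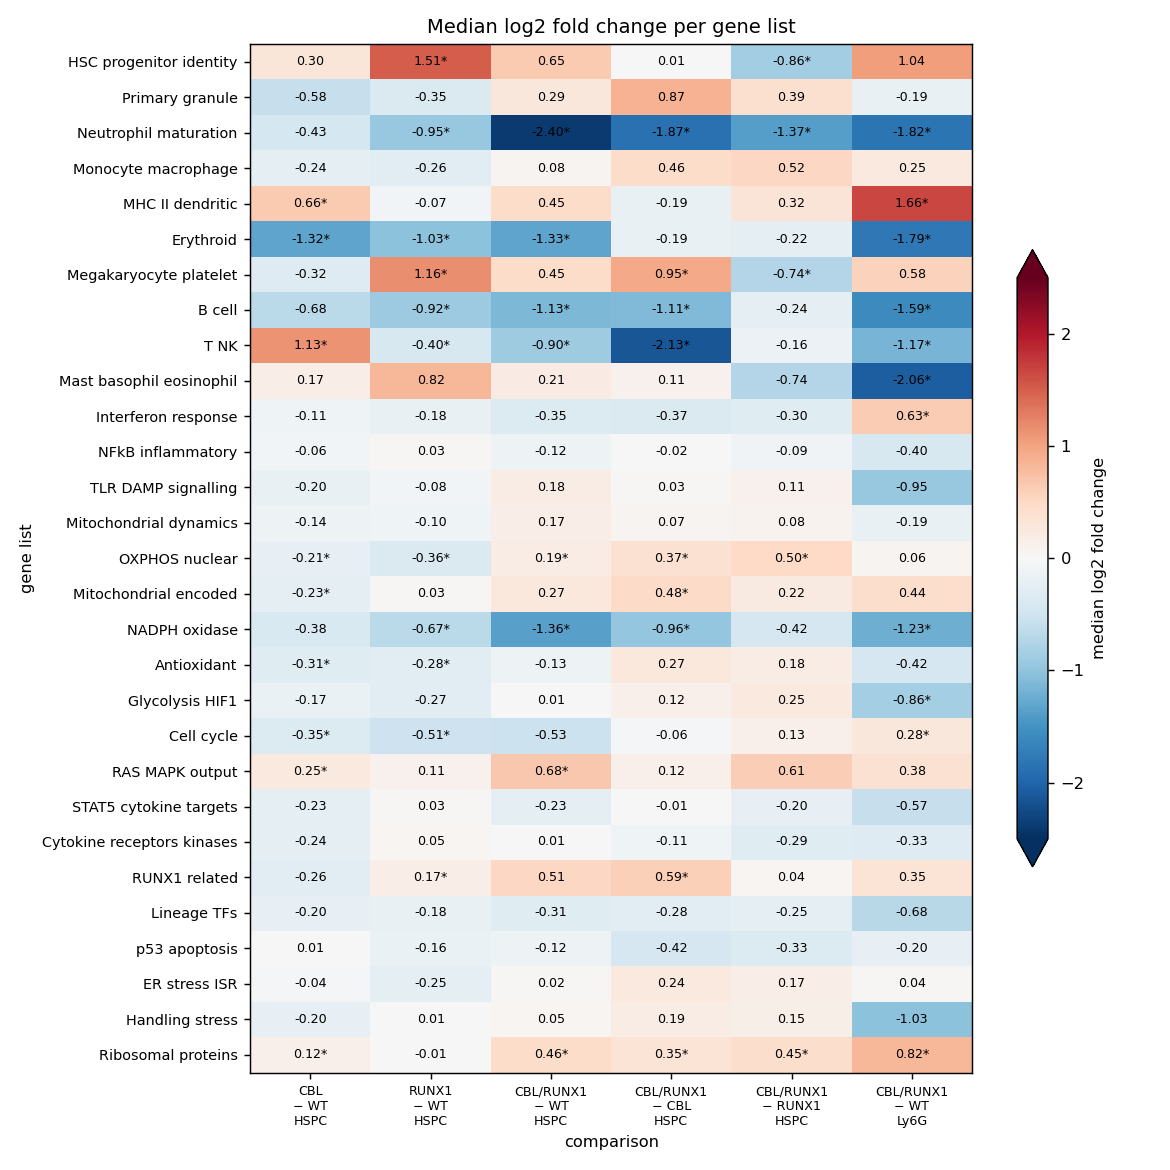
Median log2 fold change of each of the 29 tested gene lists (vertical axis) in 6 comparisons (horizontal axis), written in each cell and coloured from blue (lower in the first group named) to red (higher). An asterisk marks an adjusted p under 0.05 by camera with the preset correlation, and none of these calls held with an estimated correlation. Neutrophil maturation genes have medians of -2.40 in double mutant HSPC and -1.82 in double mutant Ly6G+ cells against wild type. The Ly6G+ median rests mostly on the first double mutant library, with mean log2 levels of 8.25 and 10.76 against 10.95 and 11.11 in wild type.

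The double mutant was set against each single mutant to ask what the second mutation adds. Against CBL mutant HSPC, T and natural killer genes fell, Tcf7 with -5.31 ± 0.25 (SE, adjusted p = 0.000739), Trbc1 with -5.10, Lck with -4.10 and Gzma with -3.49. A higher share of T and natural killer cells in the CBL mutant libraries was not tested as a source. Runx1 rose by 3.84, Ngfr by 6.30, Pf4 by 3.95 and Tfpi, a coagulation inhibitor gene, by 3.55, while Myl10 fell by 5.16 and Igkj5 by 5.32. The Ngfr rise is a lower bound too, since it starts far below the pseudocount. Of the 11 T and natural killer genes, 9 fell (10 when adjusted over the list alone), with a median of -2.13 (camera, adjusted p = 3.25e-11, and adjusted p = 0.276 with an estimated correlation). Neutrophil maturation genes had a median of -1.87, with 3 lower and 1 higher (19 and 3 when adjusted over the list alone), and adjusted p = 0.764 with an estimated correlation. The other passed lists had medians of 0.95 for megakaryocyte and platelet genes, 0.59 for RUNX1-related genes, 0.48 for mitochondrially encoded genes, 0.37 for respiratory chain genes, 0.35 for ribosomal protein genes, -1.11 for B-lineage genes and -0.96 for NADPH oxidase genes. Their calls were lost at adjusted p = 0.764 with an estimated correlation, or adjusted p = 0.778 with an estimated correlation for NADPH oxidase.

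In total 457 genes differed between double and CBL mutant HSPC, 182 higher and 275 lower. The count was 78 and 82 without wild type library 1 and 2, 10 and 27 without CBL mutant library 1 and 2, 2885 and 2890 without RUNX1 mutant library 1 and 2, and 22 and 34 without double mutant library 1 and 2. Unscaled TPM, which moved the median of all genes to 0.22, gave 230 higher and 235 lower.

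Against RUNX1 mutant HSPC, Ccnd1 rose by 3.01 ± 0.30 (SE, adjusted p = 0.0105), Spp1, the osteopontin gene, by 3.36, the immediate early gene Fos by 2.35 and Fbp1 by 2.21. The SE and p-values pool the spread of the 4 HSPC groups. They can understate that of the RUNX1 mutant pair, whose replicate difference had an SD of 0.714 against 0.304 to 0.379 in the other HSPC groups. Immunoglobulin segments fell, Igkj5 with -8.45, Igkc with -8.02, Igkj2 with -7.90 and Ighg2b with -7.89. Of 74 respiratory chain genes, 18 rose, with a median of 0.50 (46 when adjusted over the list alone), and of 71 ribosomal protein genes 8 rose, with a median of 0.45 (32 when adjusted over the list alone). Both calls were lost, at adjusted p = 0.701 with an estimated correlation. Stem and progenitor, neutrophil maturation and megakaryocyte genes had medians of -0.86, -1.37 and -0.74, with 2, 2 and 1 genes lower (2, 11 and 1 when adjusted over the list alone), also at adjusted p = 0.701 with an estimated correlation. These medians average RUNX1 mutant libraries that stood apart. Mean log2 levels in the RUNX1 mutant libraries were 4.96 and 3.38, against 3.56 and 3.11 in the double mutant, over stem and progenitor genes. They were 7.74 and 9.45 against 7.49 and 7.78 over neutrophil maturation genes, and 3.64 and 2.51 against 2.58 and 2.05 over megakaryocyte and platelet genes.

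In total 1130 genes differed between double and RUNX1 mutant HSPC, 732 higher and 398 lower. The count was 59 without either wild type library, 235 and 242 without CBL mutant library 1 and 2, 3518 and 2494 without RUNX1 mutant library 1 and 2, and 6 and 3 without double mutant library 1 and 2. The 4 libraries of these groups alone gave 0 genes by limma, and array weights gave 51.

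The non-additive term asked whether the double mutant differs from the sum of both single mutants on the log2 scale. Tcf7 lay below that sum by a term of -5.26 ± 0.35 (SE, adjusted p = 0.00849), with mean TPM of 1.92, 76.4, 2.81 and 1.07 in wild type, CBL, RUNX1 and double mutant HSPC. Tcrg-C2, a T cell receptor gene named after its value was seen, had -4.87. Whether a share of T cells in the CBL mutant libraries gave these terms was not tested. T and natural killer genes had a median term of -1.47 (1 called, and 6 lower when adjusted over the list alone), with adjusted p = 0.599 with an estimated correlation. Respiratory chain genes had a median term of 0.68 (0 called, and 44 higher when adjusted over the list alone), with adjusted p = 0.763 with an estimated correlation. Of 11 lists past the list test, 7 had positive and 4 negative terms. The other 9 had median terms of -0.95 for stem and progenitor genes, -0.92 for neutrophil maturation, 0.61 for monocytes and macrophages, 1.1001 for erythroid genes, 0.45 for mitochondrially encoded genes, 0.49 for the cell cycle and 0.31 for ribosomal proteins (-0.01 with unscaled TPM), each at adjusted p = 0.765 with an estimated correlation, and of -1.08 for mast cells, basophils and eosinophils and 0.55 for antioxidant genes, at adjusted p = 0.687 with an estimated correlation. Several of these terms depend on which RUNX1 mutant library is used, with mean log2 levels of 4.96 and 3.38 over stem and progenitor genes, 7.74 and 9.45 over neutrophil maturation genes and 2.88 and 4.75 over erythroid genes. Unscaled TPM moved the median term of all genes to -0.25. The mitochondrially encoded, cell cycle, antioxidant, monocyte, respiratory chain and erythroid terms became 0.13, 0.16, 0.23, 0.30, 0.36 and 0.77. The negative terms became larger, with -1.20 for stem and progenitor, -1.25 for neutrophil maturation, -1.37 for mast cell and -1.67 for T and natural killer genes. In total 2 genes passed, both lower, of 2400 at an unadjusted p under 0.05. The count was 0 by limma without either wild type library, either CBL mutant library or either double mutant library, and 1087 and 1976 without RUNX1 mutant library 1 and 2.

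The comparison of double mutant with wild type Ly6G+ cells asked what both mutations do in mature myeloid cells. No gene passed, and the values are given as measured. Runx3 had a log2 fold change of 3.94 ± 0.30 (SE, adjusted p = 0.163), Runx1 one of 3.05 ± 0.36 (SE, adjusted p = 0.214) and Cbl one of 0.98 ± 0.29 (SE, adjusted p = 0.333), each higher in both double mutant libraries than in both wild type ones. Interferon response genes had a median of 0.63, with Iigp1 at 2.56 and Mx1 at 2.17, and 9 of 37 were higher when adjusted over the list alone (adjusted p = 0.843 with an estimated correlation). MHC class II and dendritic genes had a median of 1.66, with Bst2 at 2.58 and H2-DMb1 at 1.59, and 10 of 16 were higher when adjusted over the list alone (adjusted p = 0.843 with an estimated correlation). Ribosomal protein genes had a median of 0.82 and cell cycle genes one of 0.28 (adjusted p = 0.843 with an estimated correlation). Their mean log2 levels were 9.97 and 9.03 in the double mutant libraries, against 8.74 and 8.64 in wild type, over ribosomal protein genes, and 5.63 and 5.15, against 5.26 and 5.01, over cell cycle genes.

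Neutrophil maturation genes had a median of -1.82, with the first double mutant library below the second by a median of -2.53, erythroid genes -1.79, mast cell, basophil and eosinophil genes -2.06, B-lineage genes -1.59, T and natural killer genes -1.17, NADPH oxidase genes -1.23 and glycolysis and HIF-1 genes -0.86 in the same comparison. These 7 lists passed the list test and were lost at adjusted p = 0.843 with an estimated correlation. Over neutrophil maturation genes the mean log2 levels were 8.25 and 10.76 in the double mutant libraries, against 10.95 and 11.11 in wild type. The second double mutant library was thus only slightly below wild type over this list. The first double mutant library was also the lower one over erythroid genes, with mean log2 levels of 2.19 and 4.19 against 5.04 and 4.86 in wild type, and over mast cell, basophil and eosinophil genes, with 1.87 and 3.57 against 4.72 and 4.60. The same held over NADPH oxidase genes, with 7.57 and 9.19 against 9.43 and 9.57, and over glycolysis and HIF-1 genes, with 5.48 and 6.14 against 6.37 and 6.43. Among the lists that did not pass were medians of 1.04 for stem and progenitor genes, with Cd34 at 3.28, -0.19 for primary granules, -0.40 for NF-kB and inflammation, -0.19 for mitochondrial dynamics, 0.06 for the respiratory chain, 0.38 for RAS-MAPK output, with Ccnd1 at 3.18, and 0.35 for RUNX1-related genes. The first double mutant library was the higher one over stem and progenitor genes, with mean log2 levels of 3.46 and 2.68 against 2.21 and 2.10 in wild type, and over RAS-MAPK output genes, with 3.30 and 2.53 against 2.42 and 2.39. Cd34 was at 195 and 40.9 TPM in the double mutant libraries and Ccnd1 at 123 and 18.0 TPM. Unscaled TPM moved the median of all genes to 0.58 and the primary granule, NF-kB and mitochondrial dynamics medians to 0.40, 0.21 and 0.39.

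In total 0 of 11744 genes passed by limma, with 1657 at an unadjusted p under 0.05 and a smallest adjusted p of 0.055. The count was 1 without either wild type library, 1258 without double mutant library 1 and 6919 without double mutant library 2, and it was 1025 in a fit of all 12 libraries. On simulated data with each gene's spread pooled over these 4 libraries, 0 of 100 genes changed by a log2 of 2 were recovered.

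The genotype by cell type term asked whether the double mutation has another effect in Ly6G+ cells than in HSPC. Mecom had a term of 5.77 ± 0.39 (SE, adjusted p = 0.00247): it fell by 5.65 in HSPC and was listed at 0.0318 and 0.165 TPM in wild type and double mutant Ly6G+ cells. Ngfr had a term of 6.89 ± 0.87 (SE, adjusted p = 0.0449), with mean TPM of 148 and 92.3 in wild type and double mutant HSPC and 0.243 and 72.9 in Ly6G+ cells, values that do not separate the mouse gene from any introduced sequence. Since 0.243 TPM lies below the pseudocount of 1, this term is a lower bound. Dusp1, an immediate early phosphatase gene, had a term of -4.81 ± 0.58 (SE, adjusted p = 0.0436), with 3.27 and 18.7 TPM in HSPC and 202 and 29.9 TPM in Ly6G+ cells. The immunoglobulin genes Ighg2c and Iglc2 had terms of 6.11 and 5.84. Interferon response genes had a median term of 1.03 (7 of 37 higher when adjusted over the list alone, and adjusted p = 0.77 with an estimated correlation). MHC class II and dendritic genes had one of 1.09 (3 of 16 higher when adjusted over the list alone, and adjusted p = 0.77 with an estimated correlation).

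Mast cell, basophil and eosinophil genes had a median term of -2.37 and glycolysis and HIF-1 genes one of -0.67, both at adjusted p = 0.77 with an estimated correlation. Cell cycle genes had a median term of 0.69 and Toll-like receptor and alarmin genes one of -0.35, both at adjusted p = 0.937 with an estimated correlation. Ribosomal protein genes had a median term of 0.35 (adjusted p = 0.942 with an estimated correlation). The double mutant Ly6G+ libraries stood apart in these lists. Toll-like receptor and alarmin genes had mean log2 levels of 4.52 and 5.80 in them against 5.74 and 5.85 in wild type Ly6G+ cells, so the second showed almost no change. The levels were 5.63 and 5.15 against 5.26 and 5.01 over cell cycle genes, 1.87 and 3.57 against 4.72 and 4.60 over mast cell, basophil and eosinophil genes, 5.48 and 6.14 against 6.37 and 6.43 over glycolysis and HIF-1 genes, and 9.97 and 9.03 against 8.74 and 8.64 over ribosomal protein genes. Immediate early and heat shock genes had one of -0.76 (adjusted p = 0.278 with an estimated correlation). In total 9 of 13155 genes passed for this term, 7 higher and 2 lower, and 8 lists passed the list test, none with an estimated correlation. The count was 3 without either wild type HSPC library, 4 and 3 without double mutant HSPC library 1 and 2, 4 and 5 without wild type Ly6G+ library 1 and 2, and 35 and 2035 without double mutant Ly6G+ library 1 and 2. Without the first RUNX1 mutant HSPC and the first double mutant Ly6G+ library together, an alternative chosen after the data were seen, it was 918.

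Wild type Ly6G+ cells were set against wild type HSPC to see how far the sorted populations differ. Primary granule genes, made at the promyelocyte stage, were lower in Ly6G+ cells: Elane by a log2 fold change of -4.10 ± 0.56 (SE, adjusted p = 0.00144) and Mpo by -3.65 ± 0.50 (SE, adjusted p = 0.00144). The progenitor gene Cd34 was lower at -2.0002, while Kit had -1.19 (adjusted p = 0.265) and Flt3 0.30 (adjusted p = 0.848). Ly6g itself had 1.99 ± 1.23 (SE, adjusted p = 0.23), with 493 TPM in HSPC and 2022 in Ly6G+ cells. The granule genes Ltf and Camp had 0.93 and -0.03, and S100a8 and S100a9 had -0.29 and 0.76, none past the test. Camp was 0.05 with RLE scaling, 0.02 with upper-quartile scaling and 0.01 with unscaled TPM.

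Of 9 primary granule genes 7 were lower in wild type Ly6G+ cells, as when adjusted over the list alone, with a median of -3.57 (adjusted p = 0.602 with an estimated correlation). Of 29 neutrophil maturation genes 10 were higher, Retnlg, Cxcr2 and Mmp8 among them at 5.01, 3.97 and 3.83 (10 when adjusted over the list alone), with a median of 1.21 (adjusted p = 0.671 with an estimated correlation). Of 28 NF-kB and inflammation genes 16 were higher and 1 lower, Il1b at 6.69 and Cxcl2 at 4.35 (17 and 1 when adjusted over the list alone, and adjusted p = 0.187 with an estimated correlation). Of 37 interferon genes 18 were higher and 2 lower (19 and 2 when adjusted over the list alone, and adjusted p = 0.621 with an estimated correlation). Of 36 cell cycle genes 31 were lower (33 when adjusted over the list alone, and adjusted p = 0.621 with an estimated correlation). Of 74 respiratory chain genes 57 were lower (61 when adjusted over the list alone, and adjusted p = 0.602 with an estimated correlation). Of 72 ribosomal protein genes 64 were lower and 2 higher (68 and 2 when adjusted over the list alone, and adjusted p = 0.621 with an estimated correlation). Of 15 immediate early and heat shock genes 9 were higher and 1 lower, Dusp1 at 5.46 and Fos at 4.19 (10 and 1 when adjusted over the list alone, and adjusted p = 0.12 with an estimated correlation).

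T and natural killer genes had a median of 1.499 (9 of 17 higher and 1 lower, 10 and 1 when adjusted over the list alone, and adjusted p = 0.12 with an estimated correlation). B-lineage genes had a median of 1.82 (7 of 17 higher, 9 when adjusted over the list alone, and adjusted p = 0.187 with an estimated correlation). MHC class II and dendritic genes had a median of 1.1045 (7 of 16 higher, as when adjusted over the list alone), and mitochondrially encoded genes one of -0.75 (8 of 13 lower, 11 when adjusted over the list alone), both at adjusted p = 0.643 with an estimated correlation. Toll-like receptor and alarmin genes had a median of 1.09 (10 of 23 higher and 2 lower, 12 and 2 when adjusted over the list alone), and cytokine receptor and kinase genes one of 0.95 (10 of 20 higher, 12 when adjusted over the list alone), both at adjusted p = 0.602 with an estimated correlation.

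In total 5140 of 13155 genes differed between the wild type populations, 2159 higher and 2981 lower in Ly6G+ cells, and 14 lists passed. The count was 2924 and 2196 without wild type HSPC library 1 and 2, and 2818 and 2372 without wild type Ly6G+ library 1 and 2. Unscaled TPM gave 1919 higher and 1277 lower.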

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

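The tests of immunoglobulin sources were chosen after the result was seen. The terms given here were planned, and each is named because its own test of a difference between effects passed.

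In HSPC, Tcf7 and Tcrg-C2 lay below the sum of both single mutants, with non-additive terms of -5.26 and -4.87, and both calls were lost whenever 1 wild type, CBL mutant or double mutant library was left out. Between Ly6G+ cells and HSPC, the effect of the double mutation differed for Mecom (5.77), Ngfr (6.89), Dusp1 (-4.81), the immunoglobulin genes Iglc2 (5.84) and Ighg2c (6.11), the predicted genes Gm10171 (3.83), Gm16569 (3.45) and Gm14686 (-2.24), and the unnamed gene ENSMUSG00000076660 (6.57). Mecom was near 0 in every Ly6G+ library, with means of 0.0318 and 0.165 TPM. The deposited values of Ngfr do not separate the mouse gene from any introduced sequence. A share of T cells in CBL mutant HSPC libraries was not tested as a source of the Tcf7 and Tcrg-C2 terms.

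Immunoglobulin genes made up 6.54% and 6.75% of wild type HSPC libraries and below 0.01% of double mutant ones, and RNA from plasma cells or other B-lineage cells in the wild type libraries could be a source. The 11 genes of a plasma cell list written before the test had a median log2 ratio of 1.22 between wild type and double mutant HSPC (TPM as deposited plus 0.1), with quartiles of 0.38 and 3.46 and 9 genes above 0, Mzb1 the highest at 5.45 (39.2 against 0.799 TPM). Its most abundant genes in double mutant HSPC were Tnfrsf13b and Txndc5, at 70.4 and 43.6 TPM against 30.1 and 40.9 TPM in wild type. The 16 B-lineage genes had a median of 1.16, with 13 above 0, and TPM scaled by TMM as in the fits gave 1.87 and 1.72 for these lists, with 10 and 15 above 0. With either scaling both medians lay between the bounds set for and against, so plasma cells and other B-lineage cells cannot be told apart as sources, a change within the progenitors was not tested, and the CD117 selection and the sort of the mutant clone, per the labels' protocols, would be the steps that remove such cells.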

How the results depend on the processing

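The alternatives with unscaled TPM, other pseudocounts, no trend and no robust moderation, array weights, and without the first RUNX1 mutant HSPC and first double mutant Ly6G+ library were chosen after the data were seen. The planned count-model alternative was not run, since the values are TPM and not counts. With 2 libraries per group, the counts of passing genes moved far under many alternatives and the cause was not tested, except that leaving out libraries also removes residual degrees of freedom. RLE scaling kept each of the 9 counts within 1.5 times its value, and upper-quartile scaling and the stricter filter kept 8 of the 9.

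Leaving out 1 library at a time gave 4 to 725 genes for CBL mutant against wild type HSPC (69 with all libraries), 1 to 3621 for RUNX1 mutant against wild type (6), 23 to 4381 for double mutant against wild type (1380), 10 to 2890 for double against CBL mutant (457), 3 to 3518 for double against RUNX1 mutant (1130), 0 to 1976 for the non-additive term (2, of 2400 at an unadjusted p under 0.05 by limma), 1 to 6919 for Ly6G+ cells (0, of 1657 at an unadjusted p under 0.05 by limma), 3 to 2035 for genotype by cell type (9) and 2196 to 7071 for the wild type populations (5140). The highest counts came without a library of a pair that stood apart, RUNX1 mutant HSPC or double mutant Ly6G+, and leaving out either library of such a pair takes the spread between them out of the fit. The list tests ranged from 84 to 95 calls, against 86.

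With the libraries of the compared groups alone the counts were 852, 1, 4632, 2234 and 0 for the 5 HSPC comparisons in the order above, and with array weights 548, 10, 4854, 2627 and 51. Array weights gave 1 gene in Ly6G+ cells and 8796 for the wild type populations. In 1 fit of all 12 libraries RUNX1 mutant against wild type gave 13 genes, double mutant against wild type 233 and Ly6G+ cells 1025. With no filter the counts were 15 for RUNX1 mutant and 440 for double mutant against wild type, 239 and 379 for double against CBL and RUNX1 mutant, 1 for the non-additive term and 67 for genotype by cell type. A change of at least a log2 of 1 left 770 genes for double mutant against wild type, 412 for double against RUNX1 mutant and 3210 for the wild type populations. Unscaled TPM gave 14 for RUNX1 mutant and 4382 for double mutant against wild type, 397 for double against RUNX1 mutant, 16 for the non-additive term, 15 for genotype by cell type and 3196 for the wild type populations. A pseudocount of 0.1 gave 40 for CBL and 3 for RUNX1 mutant against wild type. A pseudocount of 5 gave 19 for RUNX1 mutant against wild type, 4 for the non-additive term, 2 for Ly6G+ cells and 38 for genotype by cell type. Without trend and robust moderation CBL mutant against wild type gave 111, the non-additive term 11 and genotype by cell type 22. Genotype by cell type gave 18 with upper-quartile scaling and 20 with the stricter filter. Without both libraries that stood apart it gave 918, and the wild type populations gave 8189.

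The labels name no animal or batch behind a replicate number, and the data do not settle whether the numbers pair the samples, so the block was left out of the reported fits. Correlations between same-numbered residuals ranged from -0.00486 to 0.184 over the 6 pairs of HSPC groups, with 3 over 0.1, and the pair of Ly6G+ groups had 0.194. Over all 15 pairs of groups 6 lay over 0.1. The highest, 0.462, was between RUNX1 mutant HSPC and double mutant Ly6G+ cells, the 2 groups whose replicates stood far apart. With the replicate number as a block the non-additive term gave 0 genes by limma, Ly6G+ cells 7 and genotype by cell type 6, all higher, so Dusp1 and Gm14686 were not among them, and neither was Ngfr. Camera with an estimated correlation gave 0 list calls of 261 and fry 21, against 86.

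Of 3705 repeats for single named genes, 3064 kept direction and side of the threshold, 473 lost and 150 gained the call, and 18 reversed, all of genes that had not passed. With unscaled TPM, the log2 fold change turned to 0.22 for Runx1, 0.0484 for Fis1, 0.0478 for mt-Co3, 0.0938 for Inf2 and 0.0942 for mt-Co1 in CBL mutant HSPC, to 0.25 for Cbl and 0.22 for Mtfr1 in RUNX1 mutant HSPC, to 0.0167 for Mtfr1 in Ly6G+ cells and to 0.0147 for Camp between the wild type populations. Leaving out 1 library, Runx1 in CBL mutant HSPC ranged from -0.35 to 0.0289 (without CBL mutant replicate 1), Cbl in RUNX1 mutant HSPC from -0.69 to 0.15 (without RUNX1 mutant replicate 1) and Camp from -0.19 to 0.13, above 0 in 5 of the 12 fits. Camp was 0.0454 with RLE and 0.0229 with upper-quartile scaling. On simulated data with 1 pooled spread per gene, 56 to 73 of 100 genes changed by a log2 of 1 were recovered against wild type in HSPC, 24 for the non-additive term, 5 for genotype by cell type and 0 in Ly6G+ cells. The wider spread of the RUNX1 mutant HSPC and double mutant Ly6G+ pairs was averaged over the groups of a fit. Recovery in comparisons with those groups at their own spread was not measured. TPM hold no read numbers, so what depth limits could not be measured.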

Other observations

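The ratio of Runx3 to Runx1 and the tests on the first double mutant Ly6G+ library were chosen after the result was seen, while the test of shared Runx sequence was set before its result was seen.

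Runx3, another transcription factor of the RUNX family, followed Runx1 across libraries, with means of 12.8, 31.8, 107 and 294 TPM in wild type, CBL, RUNX1 and double mutant HSPC and of 5.44 and 145 TPM in wild type and double mutant Ly6G+ cells. Reads of mouse Runx1 given to Runx3 are argued against, since 9 of 4927 distinct 31-base words of Runx3 transcripts (0.183%) also occur in Runx1 transcripts. Over the 6 libraries with a RUNX1 mutant the ratio of Runx3 to Runx1 lay between 0.934 and 1.18. This is a 1.27-fold span, while Runx1 itself spanned 5.66-fold. The ratio was 1.17 and 0.952 in wild type HSPC, 2.54 and 1.99 in CBL mutant HSPC and 0.502 and 0.604 in wild type Ly6G+ cells. A ratio near 1 was thus not particular to libraries with a RUNX1 mutant. Reads of an introduced RUNX1 sequence, given to both genes, could produce a fixed ratio. The bases of any such sequence are not known, and the test of shared words covers mouse transcripts only. Joint regulation of both genes, which the genotype groups would allow, was not tested and stays open.

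The first double mutant Ly6G+ library stood apart from the second by a median log2 difference of -2.53 over the neutrophil maturation list. A lower share of neutrophils with all other cell types raised alike is argued against, since the lowest of 8 other marker lists, the erythroid one, differed by -2.39, 4 lists were clearly lower and 1 clearly higher. A library of double mutant HSPC under the Ly6G label is argued against too, since Mpo lay 16.4-fold below the lower double mutant HSPC library. The MHC class II and dendritic list differed by 0.85, and what set this library apart, biological variation between mice included, stays open.

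Ngfr, the gene of a neurotrophin receptor, differed between groups by orders of magnitude. It was 160 and 136 TPM in wild type HSPC, 0.03 and 0.043 in CBL mutant, 49.6 and 168 in RUNX1 mutant and 92.0 and 92.6 in double mutant HSPC. In Ly6G+ cells it was 0.351 and 0.135 TPM in wild type and 62.1 and 83.7 in the double mutant. The deposited values do not separate the mouse gene from any introduced sequence.

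Immediate early genes, which respond to growth factors and to tissue handling, differed in level between the populations. Fos had means of 5.84, 2.94, 3.52 and 24.8 TPM in wild type, CBL, RUNX1 and double mutant HSPC and 175 TPM in wild type Ly6G+ cells, and Dusp1 had 3.27, 3.73, 6.10, 18.7 and 202 TPM. Of 13 immediate early and heat shock genes tested in HSPC, 3 were called higher and 1 lower in the double mutant against wild type, namely Jun (1.73), Dusp1 (1.66), Egr1 (1.42) and Zfp36 (-0.98), and 4 and 2 when adjusted over the list alone. The list did not pass the list test in double mutant HSPC, with a median of 0.05. No member was called against wild type in CBL or RUNX1 mutant HSPC.

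The effect of each mutation was also compared between estimates whose group means share no library. The calls of both estimates in a pair came from the same fit, with each gene's spread pooled over all HSPC groups. A gene with a small pooled spread was more easily called in both, so the shared calls are not those of independent tests. Across 12421 genes, which are not independent replicates, CBL against wild type and double against RUNX1 mutant had a Pearson r of 0.311, and 23 of the 69 genes called in the first were called in the second, with 41 of the 69 of the same sign, against 55.6% of all genes. The second called 1130 genes in all. RUNX1 against wild type and double against CBL mutant had a Pearson r of 0.352, and 5 of the 6 genes called in the first were called in the second, with 52.4% of all genes of the same sign. Double against CBL mutant called 457 genes in all.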
